A study of Drosophila melanogaster with 22 samples.

How the data were processed

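RNA from staged follicles of flies aged 2 to 4 days was hybridised to 22 arrays, 10 groups of genotype and stage. Group, stage and replicate number were read from the sample titles; the titles of the mutant arrays also begin with the word for control, so genotype was taken from the allele name in the title. Per the labels, 10 µg of RNA was used without amplification. The labels do not say whether replicates came from separate dissections, so the p-values measure the spread between these samples and may measure technical spread.

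The deposited values are signal intensities per probe set on a linear scale, made with MAS5 per the submitters' processing notes, which give no version. Checked on the values, the mean after leaving out the top and bottom 2% was 150 in every array. Detection calls were not used here. Array medians ran from 10.0 to 28.5. Of 18952 probe sets, 183 controls were left out. A probe set was tested when its value lay above the array's median in at least 2 arrays, which kept 13223. Values were taken as log2 of the signal plus 4.95, the 25th percentile of all values.

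Gene names came from the platform's probe table: 13647 probe sets had 1 gene, 402 several and 4720 none listed there, and only the first kind were named. Symbols of 13544 were updated through gene identifiers of the RefSeq annotation of Drosophila melanogaster assembly Release 6. The tested probe sets with 1 gene numbered 10311 and covered 9391 genes. No genome build is named in the files, so no positions are printed. The neighbours of Pxt and the chromosome arms of genes were read from the same RefSeq annotation. The eggshell genes Cp7Fa, Cp7Fb, Vm26Ab and Vml and the marker gene w were not listed with a probe set of their own, and y did not pass the filter.

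Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 22 arrays, an intensity trend in the variance prior, 12 residual and 9.07 prior degrees of freedom, and a Benjamini-Hochberg adjusted p under 0.05 over the tested probe sets. The 17 comparisons were consecutive yw stages, both alleles' mean against yw, each allele against yw, the alleles against each other, and the change of the mean mutant difference between stages. Differences are log2 values ± SE from this model; signals are means ± SD.

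The 28 gene lists, the comparisons, the filter and the rule for named genes were chosen before the data were examined. Named were Pxt, the 10 largest rises and 10 largest falls per comparison of yw stages or of both alleles with yw (adjusted p under 0.05, 1 gene, no overlap between the arrays compared, higher group mean above the median of all values), the major eggshell genes, and up to 4 changed members per list; where a gene has several probe sets, the one with the highest mean was used. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated one, adjusted over lists. Lists of genes that rose or fell at least 2-fold in yw were tested in the same way, and at stage 10B also by an exact permutation test. The list of transgene marker genes had 0 measured members.

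Replicates of a group correlated at 0.933 to 0.985 across probe sets. The arrays fell into 2 signal ranges: the highest signal was 5527 to 6381 in 4 arrays (yw stage 10B replicates 1 and 2 and both f01000 stage 10B arrays) and 17697 to 39867 in the other 18. The cause of the ranges is not stated, and they are treated as a block where named. The code was tested on simulated data with 50 changed probe sets per fold size among 13223. It recovered 50% at 2-fold and 100% at 8-fold, with 6 false calls for stage 10B against 9/10A of yw; 44% at 2-fold and 92% at 8-fold, with 10 false calls for stage 12 against 10B; 34% at 2-fold and 84% at 8-fold, with 9 false calls for stage 14 against 12. For both alleles it recovered 48% at 2-fold and 98% at 8-fold, with 5 false calls at stage 10B; 42% at 2-fold and 100% at 8-fold, with 7 false calls at stage 12; 42% at 2-fold and 92% at 8-fold, with 4 false calls at stage 14.

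The alternatives tried were quantile normalization, median centring of each array, a pseudocount of 1, no filter, a filter at the 75th percentile, no intensity trend, the replicate number as a block, only the arrays of the compared groups, a minimal fold of 2, an estimated correlation, all probe sets of a gene, and leaving out each array in turn. Chosen after seeing the data were the signal range as a block, the arrays of the wider range alone, and the 3' to 5' ratio of control probe sets as a covariate.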

Results

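Transcript levels were measured on 22 Affymetrix Drosophila arrays in ovarian follicles sorted by stage. Control yw follicles were hybridised at stage 9/10A (2 arrays), 10B (4 arrays), 12 (2 arrays) and 14 (2 arrays). Follicles carrying the f01000 or the EY03052 allele of pxt, the gene of a haem peroxidase related to cyclooxygenases, were hybridised at stages 10B, 12 and 14, with 2 arrays per allele and stage. Stage 10B falls in the last phase of vitelline membrane and yolk protein production by the follicle cells, stage 12 in chorion formation, and stage 14 is the mature follicle. The number of arrays limits the precision of each value. The yw arrays show the course of follicle maturation, and the mutants were compared with yw of the same stage to ask what differs where pxt is mutant.

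Pxt itself was measured first. Its signal in yw was 4724 ± 42.8 (SD, n = 2) at stage 9/10A, 3036 ± 298 (SD, n = 4) at stage 10B, 3332 ± 265 (SD, n = 2) at stage 12 and 3839 ± 661 (SD, n = 2) at stage 14. In f01000 it was 104 ± 32.4 (SD, n = 2), 45.9 ± 25.6 (SD, n = 2) and 15.3 ± 8.07 (SD, n = 2) at stages 10B, 12 and 14. In EY03052 it was 33.9 ± 1.30 (SD, n = 2), 59.7 ± 53.1 (SD, n = 2) and 24.5 ± 4.76 (SD, n = 2). The mean log2 difference of both alleles from yw was -5.56 ± 0.29 (adjusted p = 3.0e-11) at stage 10B, -6.06 ± 0.35 (adjusted p = 3.0e-10) at stage 12 and -7.32 ± 0.35 (adjusted p = 1.0e-11) at stage 14. Every mutant array lay below every yw array, so the genotype labels and the Pxt signal go together.

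**Figure D1:**
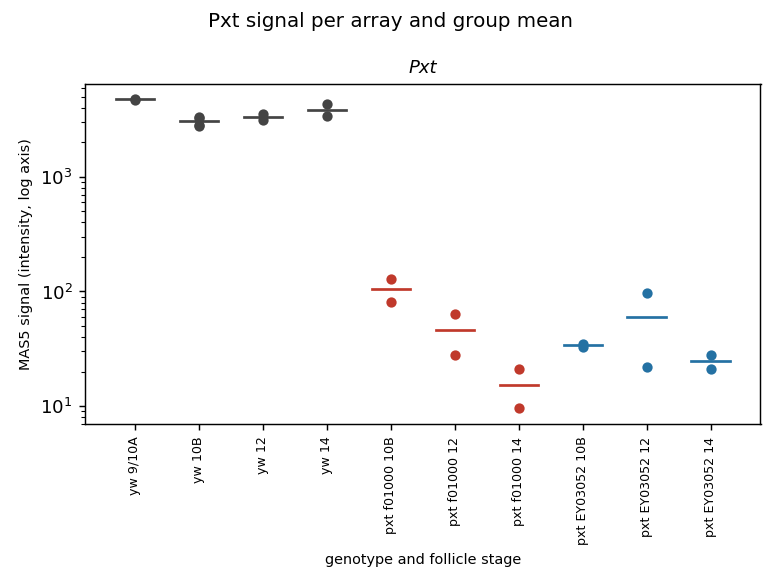
Pxt signal (MAS5 intensity, log axis) in each genotype and stage; points are arrays and short lines are group means. The yw means lie between 3036 and 4724, and the mutant means between 15.3 and 104.

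From stage 9/10A to stage 10B of yw, the eggshell genes Cp7Fc and Fcp3C were among the largest rises, and bond and ndl among the largest falls. Cp7Fc, which encodes a chorion protein, rose from a signal of 107 ± 110.2 (SD, n = 2) to 6002 ± 3000.3 (SD, n = 4), a log2 difference of 6.08 ± 0.81 (adjusted p = 2.3e-05). The eggshell gene Fcp3C rose by 5.90 ± 0.81, amd, a relative of dopa decarboxylase, by 5.94 ± 0.48, and the cadherin gene Cad74A by 5.72 ± 0.57. The other large rises were CG14187 (6.96), CG14834 (6.29), snu (5.59), Obp19c (5.48), Msr-110 (5.20) and CG13299 (5.10). The largest fall was that of bond, an enzyme of very long fatty acid synthesis, at -5.31 ± 0.71 (adjusted p = 2.3e-05). It was followed by CG31869 (-4.45), GstD2 (-3.82), Hsp68 (-3.79), Rcd2 (-3.62), fng (-3.55), CG5326 (-3.35), CG15784 (-3.07), ndl (-3.0) and CG11382 (-2.98); ndl encodes a protease and fng a glycosyltransferase that modifies Notch.

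Among the lists, by the preset correlation, those of replication and chorion genes rose and those of secretory, ribosomal and oxidative phosphorylation genes fell. With an estimated correlation only the secretory list of these passed. Of 30 measured replication genes, 20 rose and 0 fell (21 and 0 adjusted over the list alone), with dup at 1.33 and Orc1 at 1.30 (set test adjusted p = 3.9e-14, adjusted p = 0.077 with an estimated correlation). Of 10 chorion genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone), with Cp36 at 3.65 and Cp38 at 2.89 (set test adjusted p = 0.033, adjusted p = 0.42 with an estimated correlation). Of 9 vitelline membrane genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone) (set test adjusted p = 0.30, adjusted p = 0.64 with an estimated correlation). Of 23 secretory genes, 0 rose and 14 fell (0 and 15 adjusted over the list alone), among them Sec61beta at -1.20 and Spase12 at -1.29 (set test adjusted p = 2.1e-09, adjusted p = 0.028 with an estimated correlation). Of 22 detoxification and redox genes, 0 rose and 6 fell (0 and 12 adjusted over the list alone), with GstD3 at -1.30 (set test adjusted p = 7.4e-04, adjusted p = 0.028 with an estimated correlation). Of 68 oxidative phosphorylation genes, 0 rose and 43 fell (0 and 47 adjusted over the list alone), with ATPsyngamma at -1.18 (set test adjusted p = 6.5e-18, adjusted p = 0.093 with an estimated correlation).

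Of 40 cytosolic ribosomal genes, 0 rose and 31 fell (0 and 33 adjusted over the list alone), with RpS21 at -1.29 (set test adjusted p = 3.9e-14, adjusted p = 0.31 with an estimated correlation); with quantile normalization the list median was -0.030 (adjusted p = 0.12). Quantile normalization also ended the calls of the next 3 lists. Of 34 proteasome genes, 0 rose and 12 fell (0 and 15 adjusted over the list alone), with Prosbeta7 at -0.77 (set test adjusted p = 9.4e-06, adjusted p = 0.31 with an estimated correlation, quantile adjusted p = 0.12). Of 4 yolk genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone), with Yp2 at -1.45 (set test adjusted p = 0.0085, adjusted p = 0.31 with an estimated correlation, quantile adjusted p = 0.35). Of 20 lysosome and V-ATPase genes, 1 rose and 5 fell (1 and 8 adjusted over the list alone), with Vha16-1 at -1.01 (set test adjusted p = 0.0085, adjusted p = 0.11 with an estimated correlation, quantile adjusted p = 0.54). Some list calls were lost without 1 array, by adjusted p. The list lysosome and V-ATPase had 0.072 without yw stage 9/10A replicate 1. The list chorion had 0.055 to 0.40 without yw stage 9/10A replicate 2 or yw stage 10B replicate 3 or 4. No other list passed the set test, though single members did: the ecdysteroid synthesis genes spo (-2.87) and sad (-2.86) fell, as did pip (-2.69), a sulfotransferase gene of egg patterning, and Timp (-2.18), while the haem peroxidase gene CG4009 (3.67) and the caspase gene Strica (2.37) rose. The other pip probe sets did not pass, at -0.52 to 0.13.

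In this step 2235 of the 13223 probe sets passed the test, 1228 higher and 1007 lower; the split was 783 and 377 with each array centred on its median. The 4 yw arrays of stage 10B came in pairs of unlike signal range, and with the range as a block the count was 1888. The count was 656 without yw stage 9/10A replicate 1. Leaving out 1 array brought the adjusted p of some named genes past 0.05. GstD3, pip, spo, CG11382 and Hsp68 had 0.058 to 0.091 without yw stage 9/10A replicate 1. Yp2 had 0.078 to 0.081 without yw stage 9/10A replicate 1 or 2. Cp36 had 0.13 without yw stage 9/10A replicate 2. Cp38 had 0.051 to 0.34 without yw stage 9/10A replicate 2 or yw stage 10B replicate 4. On the Act5C control probe sets the 3' over 5' signal ratio was 9.39 to 12.5 in the stage 9/10A arrays and 2.49 to 4.24 in the stage 10B arrays of yw, while that of GAPDH was 2.69 to 3.02 and 3.22 to 3.79. With the mean 3' to 5' ratio as a covariate the chorion list of this step had an adjusted p of 0.11 and Cp38 of 0.053. With the block, Yp2 had an adjusted p of 0.064.

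From stage 10B to stage 12 of yw, vitelline membrane and yolk protein transcripts gave way to those of the chorion. Vm32E, a vitelline membrane protein gene, fell from 6491 ± 2941 (SD, n = 4) to 56.8 ± 62.5 (SD, n = 2), a log2 difference of -7.11 ± 0.80 (adjusted p = 3.9e-06). The genes psd, Vm26Ac and Fcp3C of the vitelline membrane list fell, with log2 differences of -5.57 ± 0.34, -5.13 ± 0.49 and -4.76 ± 0.81. The yolk protein genes Yp1, Yp2 and Yp3 fell likewise, at -5.17 ± 0.61, -4.89 ± 0.37 and -4.30 ± 0.40. The largest rises were CG13083 (8.59) and CG13084 (8.12) and the mucin gene Muc4B, which went from 15.6 ± 7.39 (SD, n = 4) to 5439 ± 254 (SD, n = 2), a log2 difference of 8.12 ± 0.48 (adjusted p = 7.4e-10). The chorion gene Femcoat rose by 6.42 ± 0.58 and yellow-g by 5.91 ± 0.97, next to CG10163 (7.74), CG15570 (7.29), CG15571 (7.05), CG13114 (6.66) and CG12716 (5.96). Further falls were CG8303 (-4.68), ndl (-4.63) and osy (-4.20).

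Of 9 vitelline membrane genes, 0 rose and 5 fell (0 and 6 adjusted over the list alone) (set test adjusted p = 4.5e-15, adjusted p = 0.016 with an estimated correlation). Of 10 chorion genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone), including Cp16 at 4.79 and Cp18 at 4.43 (set test adjusted p = 2.4e-11, adjusted p = 0.024 with an estimated correlation). Of 4 yolk genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone), all but the receptor gene yl (set test adjusted p = 3.2e-09, adjusted p = 0.023 with an estimated correlation). Of 4 genes of follicle rupture, 2 rose and 0 fell (2 and 0 adjusted over the list alone): Nox, an NADPH oxidase gene, at 2.41 and the protease inhibitor gene Timp at 2.32 (set test adjusted p = 5.1e-04, adjusted p = 0.024 with an estimated correlation). Of 23 secretory genes, 0 rose and 4 fell (0 and 6 adjusted over the list alone), with TRAM at -0.89 (set test adjusted p = 3.2e-09, adjusted p = 0.016 with an estimated correlation). Of 20 lysosome and V-ATPase genes, 0 rose and 2 fell (1 and 7 adjusted over the list alone) (set test adjusted p = 8.6e-06, adjusted p = 0.016 with an estimated correlation). Of 13 ecdysone response genes, 0 rose and 3 fell (0 and 4 adjusted over the list alone), with 1 probe set of the transcription factor gene br at -3.63 (set test adjusted p = 0.0038, adjusted p = 0.13 with an estimated correlation). The other br probe sets did not pass, at -1.25 to 0.33, nor did the second of Nox, at 0.48.

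No cytosolic ribosomal gene passed the test in either direction (0 of 40), and the list's median was 0.45 (set test adjusted p = 2.6e-05, adjusted p = 0.52 with an estimated correlation). With the signal range as a block its adjusted p was 0.53, and with quantile normalization the median was -0.0037 (adjusted p = 0.86). No other list passed without the block. With it the gut markers did, at a median of -1.11 (set test adjusted p = 0.0039 with the preset correlation, 0.052 without the block). Egfr fell (-1.93), as did the muscle gene Prm (-3.45), while CG4009 (3.89) and srp (3.48), a GATA factor gene of the blood cell list, rose. In this step 449 of the 13223 probe sets passed the test, 202 higher and 247 lower, and 248 with the signal range as a block. The count was 191 without yw stage 12 replicate 1 and 213 without yw stage 12 replicate 2.

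From stage 12 to stage 14 of yw, the late chorion genes Cp15, Cp16 and Cp18 rose while Cp7Fc, yellow-g, yellow-g2 and dec fell. Cp15, a late chorion protein gene, rose from 461 ± 398 (SD, n = 2) to 25221 ± 9954 (SD, n = 2), a log2 difference of 6.03 ± 0.81 (adjusted p = 7.9e-05). The relaxin-like peptide gene Ilp8 rose by 5.96 ± 0.46 (adjusted p = 2.8e-08), and CG6508 by 6.66 ± 0.51 (adjusted p = 2.8e-08). The other large rises were atilla (5.43), CG15721 (4.98), Muc12Ea (4.70), CG32642 (4.47), CG1698 (4.28), Nha1 (4.10) and Tg (4.09); Nha1 encodes a sodium/proton exchanger and Tg transglutaminase. The log2 differences of the early chorion gene Cp7Fc, of yellow-g2 and of the eggshell gene dec were -6.98 ± 0.93, -6.45 ± 1.02 and -5.92 ± 0.90. The other large falls were CG14834 (-7.29), CG43333 (-6.45), CG1077 (-6.32), CG10163 (-6.09), CG13114 (-6.07), Muc4B (-5.79) and Obp19c (-5.64). The second Obp19c probe set did not pass, at -0.42.

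Of 10 chorion genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone): Cp15, Cp16 (2.60) and Cp18 (3.67) against Cp7Fc, yellow-g (-4.88) and yellow-g2 (set test adjusted p = 0.998, adjusted p = 0.999 with an estimated correlation). Of 9 vitelline membrane genes, 1 rose and 1 fell (2 and 2 adjusted over the list alone) (set test adjusted p = 0.80, adjusted p = 0.999 with an estimated correlation). Nox rose again on 1 of 2 probe sets (1.90, the other 0.27), and Timp fell (-2.63), as did CG4009 (-4.97), Cad74A (-4.28) and srp (-3.67). Catalase, Cat, rose by 1.44 ± 0.26. Small shifts of whole lists passed with the preset correlation and not with an estimated one. These were oxidative phosphorylation (median 0.19, 0 members past the test (0 higher and 0 lower adjusted over the list alone), set test adjusted p = 2.4e-04, adjusted p = 0.61 with an estimated correlation), the proteasome (median 0.19, 0 members (0 higher and 0 lower adjusted over the list alone), set test adjusted p = 0.017, adjusted p = 0.68 with an estimated correlation) and the lysosome and V-ATPase list (median 0.18, 1 higher and 0 lower (1 higher and 0 lower adjusted over the list alone), set test adjusted p = 0.043, adjusted p = 0.36 with an estimated correlation). The yolk genes (median 1.05, 0 members (1 higher and 0 lower adjusted over the list alone), set test adjusted p = 0.017, adjusted p = 0.49 with an estimated correlation) and the gut markers (median 1.21, 0 members (0 higher and 0 lower adjusted over the list alone), set test adjusted p = 0.043, adjusted p = 0.36 with an estimated correlation) behaved alike. With the 3' to 5' ratio of control probe sets as a covariate, all 5 calls were lost (adjusted p = 0.088 for yolk and 0.094 for each of the others); the Act5C ratio was 2.61 to 3.37 at stage 12 and 5.18 to 8.19 at stage 14. These calls were lost without 1 array, by the preset adjusted p. The list yolk had 0.097 to 0.29 without yw stage 12 replicate 1 or yw stage 14 replicate 1. The list lysosome and V-ATPase had 0.097 to 0.68 without yw stage 12 replicate 1 or 2 or yw stage 14 replicate 1. The list gut markers had 0.067 to 0.20 without yw stage 12 replicate 1 or yw stage 14 replicate 1 or 2. The lists oxidative phosphorylation and proteasome had 0.39 to 0.68 without yw stage 14 replicate 1.

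In this step 270 of the 13223 probe sets passed the test, 107 higher and 163 lower. Centring each array on its median moved the median over all probe sets from -0.021 to 0.080. The count was 123 without yw stage 12 replicate 1 and 137 without yw stage 12 replicate 2. It was 145 without yw stage 14 replicate 2. Leaving out 1 array brought the adjusted p of some named genes past 0.05. Muc12Ea and Cp18 had 0.065 to 0.25 without yw stage 12 replicate 1 or yw stage 14 replicate 2. Cp16 and Nox had 0.069 to 0.20 without yw stage 12 replicate 1 or 2 or yw stage 14 replicate 1 or 2. yellow-g had 0.13 to 0.30 without yw stage 12 replicate 1 or 2 or yw stage 14 replicate 2. Cat, CG4009 and CG1077 had 0.054 to 0.15 without yw stage 14 replicate 2.

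**Figure D2:**
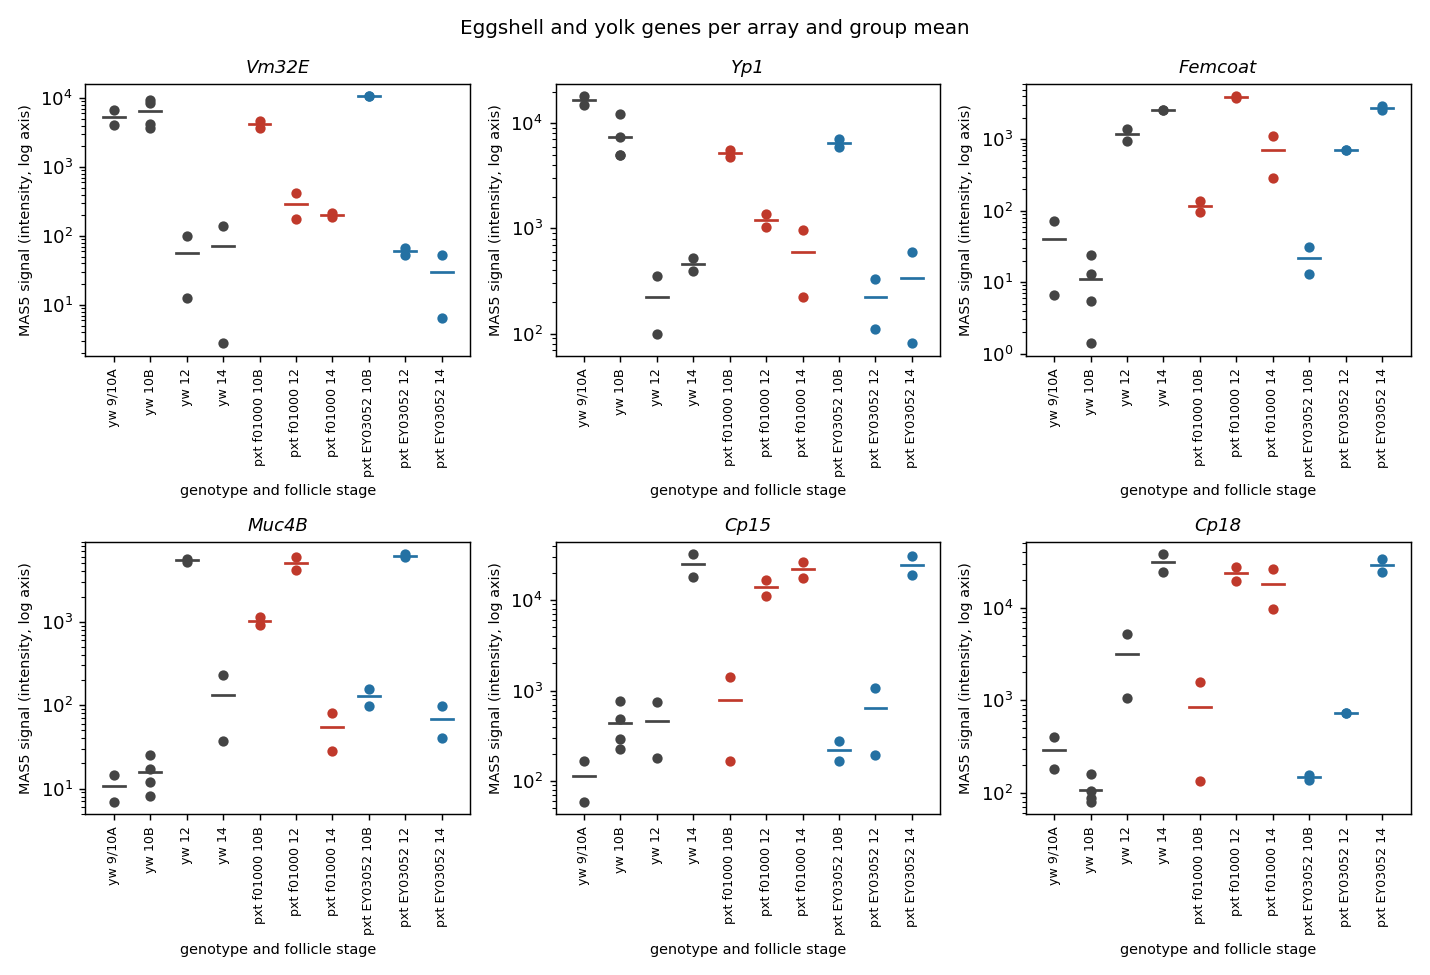
Signals (MAS5 intensity, log axis) of Vm32E, Yp1, Femcoat, Muc4B, Cp15 and Cp18 in each genotype and stage; points are arrays and short lines are group means. In yw Cp15 goes from 461 at stage 12 to 25221 at stage 14, and in f01000 it is at 13977 at stage 12.

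At stage 10B, the mean of both pxt alleles was higher than yw for several genes that rise later in yw, and lower for glutathione transferase genes. Muc4B was at 1027 ± 177 (SD, n = 2) in f01000 and 128 ± 41.1 (SD, n = 2) in EY03052 against 15.6 ± 7.39 (SD, n = 4) in yw, a mean log2 difference of 4.21 ± 0.39 (adjusted p = 5.2e-07). The chorion list genes yellow-g2, yellow-g and Femcoat were higher in the mean by 3.38 ± 0.72, 3.32 ± 0.79 and 2.02 ± 0.48. With the signal range as a block, each passed in f01000 and none in EY03052 (adjusted p = 0.55, 0.71 and 0.94). The alleles did not differ in them past the threshold with the block (adjusted p = 0.88, 0.88 and 0.49). CG13937 was higher by 4.62 ± 0.26 (adjusted p = 1.5e-10), and the other large differences were CG10163 (3.95), hog (3.72), CG13114 (3.42), CG11357 (3.41), CG15570 (3.37) and CG5096 (3.21). With the block, CG13937, CG11357 and CG5096 passed in each allele. CG10163, hog, CG13114 and CG15570 passed in f01000 and not in EY03052 (adjusted p = 0.80, 0.080, 0.60 and 0.91). Of the latter, only hog differed between the alleles (adjusted p = 0.032). GstD1 was at 431 ± 7.29 (SD, n = 2) and 221 ± 29.0 (SD, n = 2) in the mutants against 5612 ± 1958 (SD, n = 4) in yw, a difference of -4.09 ± 0.19 (adjusted p = 8.3e-12). Besides Pxt, the other lower genes were CG12773 (-4.68), CG17470 (-3.0), GstD9 (-2.26), Oseg5 (-2.08), GstD3 (-1.94), CG31674 (-1.92), spen (-1.69) and CG14102 (-1.52); the second spen probe set was at 0.015.

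Of 22 detoxification and redox genes, 0 higher and 5 lower (0 and 6 adjusted over the list alone), GstD1, GstD9, GstD3 and GstE7 (-0.70) among them (set test adjusted p = 0.0011, adjusted p = 0.041 with an estimated correlation). Of 10 chorion genes, 3 higher and 0 lower (5 and 0 adjusted over the list alone) (set test adjusted p = 0.0011, adjusted p = 0.57 with an estimated correlation). In the mean of both alleles, the late chorion genes Cp15 and Cp18 differed by -0.28 ± 0.57 (adjusted p = 0.95) and 1.28 ± 0.53 (adjusted p = 0.24). With the signal range as a block, the late chorion gene Cp16 was at 2.27 (limma adjusted p = 0.014) in f01000. In EY03052 it was at 0.032 and did not pass, and the alleles did not differ in it past the threshold (adjusted p = 0.26). Cp15 and Cp18 did not pass in f01000 with the block, at 0.050 and 2.21. No other list passed. Of the vitelline membrane list only fs(1)N passed, at -0.41, and no yolk protein gene did (Yp1 -0.25, Yp2 -0.058, Yp3 -0.56). The peroxidase gene Duox was lower (-1.31), and 1 of 6 blood cell genes, srp, was higher (1.69).

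In this comparison 579 of the 13223 probe sets passed the test, 351 higher and 228 lower; the split was 134 and 188 with each array centred on its median, a scaling that moved the median over all probe sets from 0.024 to -0.16. With the signal range as a block the count was 669, of which 578 were among the 579. The count was 364 without f01000 stage 10B replicate 1 and 312 without f01000 stage 10B replicate 2. Leaving out 1 array brought the adjusted p of some named genes past 0.05. Femcoat had 0.051 to 0.089 without yw stage 10B replicate 1 or 4, f01000 stage 10B replicate 1 or EY03052 stage 10B replicate 2. fs(1)N had 0.052 to 0.15 without yw stage 10B replicate 1, 2 or 3, f01000 stage 10B replicate 2 or EY03052 stage 10B replicate 2. CG31674 had 0.055 to 0.11 without yw stage 10B replicate 1 or 2, f01000 stage 10B replicate 2 or EY03052 stage 10B replicate 1 or 2. CG15570 had 0.051 to 0.065 without yw stage 10B replicate 2, f01000 stage 10B replicate 1 or EY03052 stage 10B replicate 1 or 2. yellow-g had 0.053 to 0.060 without yw stage 10B replicate 2, f01000 stage 10B replicate 1 or 2 or EY03052 stage 10B replicate 1. GstE7 had 0.052 to 0.11 without yw stage 10B replicate 2 or 4, f01000 stage 10B replicate 1 or 2 or EY03052 stage 10B replicate 1.

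At stage 12, hog and CG13937 were the largest rises in both alleles together, and Pxt and GstD1 the largest falls. GstD1 was lower by a log2 difference of -4.93 ± 0.24 (adjusted p = 1.2e-11) and GstD9 by -3.35 ± 0.53. The other lower genes besides Pxt were CG12773 (-3.86), CG17470 (-3.51), CG30334 (-2.67), Ubi-p5E (-2.56), Oseg5 (-2.55), CanA-14F (-2.07) and spen (-1.82). Some of these means describe neither allele. In f01000 and EY03052, Ubi-p5E was at -4.82 and -0.30, CanA-14F at -3.28 and -0.86, and CG30334 at -3.76 and -1.59. For CG30334 the difference between the alleles had an adjusted p of 0.085. hog was higher by 4.81 ± 0.42 (adjusted p = 2.5e-07) and CG13937 by 4.37 ± 0.32 (adjusted p = 1.8e-08). They were followed by tut (3.79), TfIIA-S-2 (3.78), CG11357 (3.73), CG5096 (3.13), dany (2.97), CG10013 (2.78), CG5953 (2.71) and Cyp4p3 (2.68); TfIIA-S-2 encodes a subunit of a general transcription factor and Cyp4p3 a cytochrome P450. Cp15 was higher on average by 2.76 ± 0.70 (adjusted p = 0.041), with 5.20 in f01000 and 0.33 in EY03052. The second probe set of spen did not pass, at 0.27.

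Of 22 detoxification and redox genes, 1 higher and 3 lower (1 and 4 adjusted over the list alone), with GstD1, GstD9 and GstD3 (-1.66) lower and GstE1 (1.0) higher (set test adjusted p = 0.15, adjusted p = 0.64 with an estimated correlation). Of 10 chorion genes, 1 higher and 0 lower (1 and 0 adjusted over the list alone) (set test adjusted p = 0.54, adjusted p = 0.97 with an estimated correlation). The vitelline membrane list had 0 members past the test (0 higher and 0 lower adjusted over the list alone) (set test adjusted p = 0.89, adjusted p = 0.99 with an estimated correlation). The proteasome list was lower (median -0.19, 0 of 34 members past the test (0 higher and 0 lower adjusted over the list alone), set test adjusted p = 0.046, adjusted p = 0.97 with an estimated correlation); its adjusted p was 0.077 with median centring and past 0.05 without 1 array, 0.060 to 0.17 without yw stage 12 replicate 1 or 2, f01000 stage 12 replicate 2 or EY03052 stage 12 replicate 1 or 2. No other list passed. Diap2, an inhibitor of apoptosis, was lower (-0.79), as was Duox (-1.27), and 1 gut gene, LManII, was higher (1.01).

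In this comparison 288 of the 13223 probe sets passed the test, 181 higher and 107 lower. The count was 70 without yw stage 12 replicate 1 and 92 without yw stage 12 replicate 2. It was 845 without f01000 stage 12 replicate 1 and 160 without EY03052 stage 12 replicate 1. It was 166 without EY03052 stage 12 replicate 2. Leaving out 1 array brought the adjusted p of some named genes past 0.05. Cp15 and CG30334 had 0.050 to 0.71 without yw stage 12 replicate 1, f01000 stage 12 replicate 2 or EY03052 stage 12 replicate 2. Cyp4p3, GstE1 and Oseg5 had 0.057 to 0.23 without yw stage 12 replicate 1 or 2. LManII and spen had 0.052 to 0.42 without yw stage 12 replicate 1 or 2, f01000 stage 12 replicate 1 or EY03052 stage 12 replicate 1 or 2. Diap2 had 0.064 to 0.21 without yw stage 12 replicate 1 or 2 or EY03052 stage 12 replicate 2. CanA-14F had 0.081 without yw stage 12 replicate 1.

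At stage 14, CG13937 and hog were again the largest rises in both alleles together, and Pxt, GstD1 and CG12773 the largest falls. GstD1 was lower by a log2 difference of -4.37 ± 0.24 (adjusted p = 8.9e-11) and CG12773 by -4.36 ± 0.34 (adjusted p = 3.7e-08). Lower levels were also measured for CG17470 (-3.59), Ubi-p5E (-2.35), Osi19 (-2.17), Prx6c (-1.97), CG14102 (-1.80) and CG42694 (-1.69) and the yolk protein gene Yp3 (-1.63). Of these, Prx6c encodes a peroxiredoxin, and Ubi-p5E was at -4.20 in f01000 and -0.51 in EY03052. CG13937 was higher by 4.22 ± 0.32 (adjusted p = 3.0e-08), followed by hog (3.82), TfIIA-S-2 (3.65), CG11357 (3.59), tut (3.14), CG5096 (3.09), CG10013 (2.84), CG42857 (2.82), Cyp6a17 (2.80) and CG5953 (2.70). The late chorion genes Cp15 (-0.084, adjusted p = 0.99), Cp16 (-0.69, adjusted p = 0.73) and Cp18 (-0.50, adjusted p = 0.89) did not pass.

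Of 22 detoxification and redox genes, 0 higher and 2 lower (0 and 3 adjusted over the list alone), GstD1 and GstD3 (-1.43) (set test adjusted p = 0.0065, adjusted p = 0.067 with an estimated correlation). The chorion list was lower as a whole (median -0.78) with 0 of 10 members past the test (0 higher and 0 lower adjusted over the list alone) (set test adjusted p = 0.017, adjusted p = 0.98 with an estimated correlation); its adjusted p was 0.19 with quantile normalization and past 0.05 without 1 array, 0.057 to 0.80 without yw stage 14 replicate 1, f01000 stage 14 replicate 2 or EY03052 stage 14 replicate 1. By allele, Cp36 and Cp38 were at -3.42 and -3.35 in f01000 and at 0.30 and 0.13 in EY03052, and Cp19 at -1.45 and -0.062. The differences between the alleles had adjusted p = 0.057, 0.054 and 0.21, and 0.048, 0.049 and 0.16 with the signal range as a block. The Act5C 3' over 5' ratio was 16.4 in f01000 stage 14 replicate 2 and 5.64 in replicate 1, and without replicate 2 the chorion list had an adjusted p of 0.57. No other list passed. Duox (-1.41) and Diap2 (-0.98) were lower. In this comparison 216 of the 13223 probe sets passed the test, 135 higher and 81 lower; the split was 56 and 51 with each array centred on its median, which moved the median over all probe sets from 0.028 to -0.11. The count was 108 without yw stage 14 replicate 1 and 98 without yw stage 14 replicate 2. Leaving out 1 array brought the adjusted p of some named genes past 0.05. CG10013, Diap2 and GstD3 had 0.057 to 0.098 without yw stage 14 replicate 1. Yp3 and Osi19 had 0.13 to 0.38 without yw stage 14 replicate 1 or 2, f01000 stage 14 replicate 1 or EY03052 stage 14 replicate 2. CG42694 had 0.050 to 0.41 without yw stage 14 replicate 1 or 2, f01000 stage 14 replicate 1 or 2 or EY03052 stage 14 replicate 1 or 2. Prx6c had 0.083 to 0.24 without yw stage 14 replicate 1 or 2 or EY03052 stage 14 replicate 1. Cyp6a17 had 0.11 without yw stage 14 replicate 2.

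Some genes differed from yw in each allele at each stage. Of 35 probe sets past the test in all 6 allele and stage comparisons with 1 direction, 18 were higher and 17 lower; they were singled out after their values were seen. The mean log2 difference over the 6 comparisons was lowest for a probe set with no gene name (-6.48), next to Pxt (-6.31), and then for GstD1 (-4.46), CG12773 (-4.30) and CG17470 (-3.37). The peroxidase gene Duox (-1.33), the chitinase gene Cht2 (-1.49), the paxillin gene Pax (-1.53), Cyp4p2 (-1.32), Prosap (-0.95) and TfIIFbeta (-0.94) were lower too. Higher were CG13937 (4.40), CG11357 (3.58), TfIIA-S-2 (3.46), tut (3.18), CG5096 (3.14), CG10013 (2.85) and CG5953 (2.47), the dynactin subunit gene DCTN3-p24 (1.69) and the calcium channel gene Orai (1.31). In the mean of both alleles, 123 probe sets passed at all 3 stages in 1 direction, 74 higher and 49 lower.

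**Figure D3:**
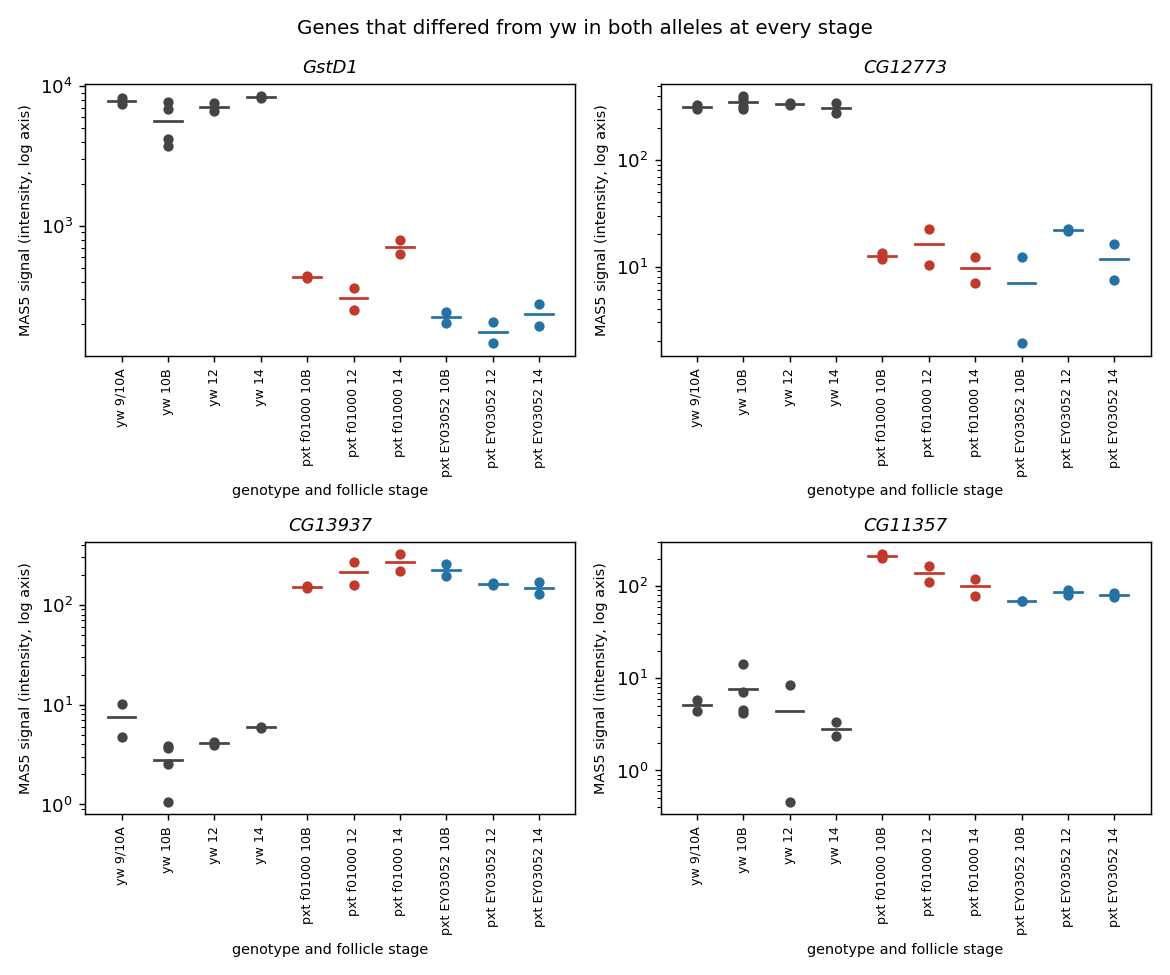
Signals (MAS5 intensity, log axis) of GstD1, CG12773, CG13937 and CG11357 in each genotype and stage; points are arrays and short lines are group means. GstD1 means lie between 5612 and 8420.1 in yw and between 175 and 709 in the mutants.

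The alleles were then taken one at a time and against each other. At stage 10B, Muc4B was higher by 5.71 (adjusted p = 1.0e-07) in f01000 and 2.72 (adjusted p = 0.0033) in EY03052. The difference between the alleles was 2.99 ± 0.56 (adjusted p = 0.0021), and that of hog was 3.09 ± 0.49 (adjusted p = 6.0e-04). With the signal range as a block, Muc4B differed between the alleles by 3.77 (adjusted p = 0.036) and in EY03052 from yw by 2.33 (adjusted p = 0.069). For CG10163, CG13114 and yellow-g the EY03052 values were 2.40 (adjusted p = 0.23), 2.50 (adjusted p = 0.15) and 2.83 (adjusted p = 0.20). Femcoat was at 3.14 in f01000 and 0.90 (adjusted p = 0.52) in EY03052, a difference of 2.25 ± 0.67 (adjusted p = 0.036), and srp was at 2.73 in f01000 and 0.65 (adjusted p = 0.54) in EY03052, a difference of 2.08 ± 0.51 (adjusted p = 0.012). The alleles differed as well, f01000 given first, in CG11357 (4.18 and 2.64), CG5096 (4.29 and 2.13), CG14102 (-1.10 and -1.93) and Pxt (-4.83 and -6.29). With the block none of these 6 differences passed, the adjusted p being 0.094 to 0.49. GstD1 was lower in EY03052 than in f01000, with a difference of 0.95 ± 0.28 (adjusted p = 0.030). The counts were 1277 probe sets for f01000 against yw, 160 for EY03052 against yw and 1418 between the alleles. Both f01000 arrays had the lower signal range and both EY03052 arrays the wider one, and with the range as a block the counts were 849, 74 and 95.

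At stage 10B, 52 probe sets were higher and 39 lower in each allele by itself. Independent lists of these sizes would share 4.21 and 3.53. In 20 simulations of unchanged groups with simulated, shared yw arrays the mean was 0 and 0. Unchanged groups leave few calls to share, so this does not show what shared controls bring to lists of these sizes. The simulated arrays also had no signal ranges. Of the measured probe sets 1 passed with opposite directions in the alleles. The covariance of the alleles' log2 differences was 0.0543, against 0.0614 simulated and 0.0739 with the yw arrays split between the alleles. The correlations across probe sets, which are not independent replicates, were 0.169, 0.337 and 0.245. The EY03052 differences split into 85 higher and 75 lower, and 41 and 65 with each array centred on its median. Those between the alleles split into 731 higher in f01000 and 687 lower, and 332 and 177 with each array centred on its median. Over all probe sets the median was -0.082, and -0.22 with each array centred on its median, for f01000 and 0.12, and -0.10 with each array centred on its median, for EY03052; quantile normalization took it to 0.0034 for EY03052 and between the alleles from -0.22 to -0.041. The f01000 count was 582 without f01000 stage 10B replicate 1 and 466 without f01000 stage 10B replicate 2. The EY03052 count was 96 without yw stage 10B replicate 2 and 255 without yw stage 10B replicate 3. It was 68 without EY03052 stage 10B replicate 1 and 74 without EY03052 stage 10B replicate 2. The count between alleles was 436 without f01000 stage 10B replicate 1 and 305 without f01000 stage 10B replicate 2. It was 479 without EY03052 stage 10B replicate 1 and 646 without EY03052 stage 10B replicate 2.

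At stage 12, the late chorion genes Cp15, Cp16 and Cp18 were higher than yw in f01000 and not past the test in EY03052. Cp15 was at 13977 ± 4174 (SD, n = 2) in f01000, 637 ± 623 (SD, n = 2) in EY03052 and 461 ± 398 (SD, n = 2) in yw. The f01000 differences from yw were 5.20 (adjusted p = 3.6e-04) for Cp15, 3.29 (adjusted p = 0.0082) for Cp18 and 2.45 (adjusted p = 0.014) for Cp16. Those of EY03052 were 0.33 (adjusted p = 0.999), -1.68 (adjusted p = 0.76) and -1.43 (adjusted p = 0.69), so Cp18 and Cp16 lay above yw in f01000 and below it in EY03052. The alleles differed by 4.87 ± 0.81 (adjusted p = 0.0014) in Cp15, 4.97 ± 0.74 (adjusted p = 4.6e-04) in Cp18 and 3.88 ± 0.60 (adjusted p = 6.7e-04) in Cp16. Yp1 differed by 2.60 ± 0.71 (adjusted p = 0.039) and Cp19 by 1.95 ± 0.55 (adjusted p = 0.046). The polyubiquitin gene Ubi-p5E was lower in f01000, at -4.82 (adjusted p = 7.7e-11), and at -0.30 (adjusted p = 0.999) in EY03052; the alleles differed by -4.52 ± 0.25 (adjusted p = 2.7e-10). CanA-14F was at -3.28 in f01000 and -0.86 (adjusted p = 0.84) in EY03052, a difference of -2.42 ± 0.41 (adjusted p = 0.0015). With f01000 given first, hog (6.72 and 2.90), tut (5.39 and 2.20), dany (3.79 and 2.15), CG5953 (3.25 and 2.16) and CG17470 (-4.37 and -2.64) differed too. On the Act5C control probe sets, the 3' over 5' signal ratio was 24.1 in f01000 stage 12 replicate 2 and 2.10 to 16.4 in the other arrays.

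The stage 12 counts were 1066 for f01000 against yw, 72 for EY03052 against yw and 578 between the alleles. At this stage 33 probe sets were higher and 25 lower in each allele by itself. Independent lists of these sizes would share 1.59 and 1.30. In 20 simulations of unchanged groups with simulated, shared yw arrays the mean was 0 and 0, where few calls are left to share. The covariance of the alleles' log2 differences was 0.170, against 0.120 simulated. Their correlation was 0.478, below the simulated 0.499. The 2 yw arrays were not split between the alleles at this stage, so part of the overlap may come from the shared controls. Without f01000 stage 12 replicate 2, Cp16 differed from yw in f01000 by 2.55 ± 0.74 (adjusted p = 0.059). For f01000 the median over all probe sets was 0.023, and -0.094 with each array centred on its median. The f01000 count was 339 without yw stage 12 replicate 1 and 430 without yw stage 12 replicate 2. It was 1786 without f01000 stage 12 replicate 1 and 494 without f01000 stage 12 replicate 2. The EY03052 count was 35 without yw stage 12 replicate 1 and 44 without yw stage 12 replicate 2. It was 33 without EY03052 stage 12 replicate 1 and 36 without EY03052 stage 12 replicate 2. The count between alleles was 1353 without f01000 stage 12 replicate 1 and 259 without f01000 stage 12 replicate 2. It was 128 without EY03052 stage 12 replicate 1 and 131 without EY03052 stage 12 replicate 2.

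At stage 14, Ubi-p5E was again lower in f01000, at -4.20 (adjusted p = 2.4e-10), and at -0.51 (adjusted p = 0.62) in EY03052, with a difference of -3.68 ± 0.25 (adjusted p = 5.0e-09) between the alleles. CG42857 was at 4.11 in f01000 and 1.53 (adjusted p = 0.36) in EY03052, a difference of 2.58 ± 0.54 (adjusted p = 0.011). hog was at 1.97 (adjusted p = 0.077) in EY03052 and differed by 3.69 ± 0.49 (adjusted p = 1.4e-04), tut by 2.26 ± 0.34 (adjusted p = 6.2e-04) and GstD1 by 1.59 ± 0.28 (adjusted p = 0.0020). Further differences, with f01000 given first, were those of CG5953 (3.26 and 2.14), Duox (-1.77 and -1.05), GstD3 (-0.79 and -2.07), CG14102 (-1.06 and -2.54) and CG17470 (-4.77 and -2.41). The counts were 557 for f01000 against yw, 81 for EY03052 against yw and 408 between the alleles. The EY03052 differences split into 44 higher and 37 lower, and 23 and 29 with each array centred on its median; those between the alleles into 227 higher in f01000 and 181 lower, and 114 and 57 with each array centred on its median. At stage 14, 34 probe sets were higher and 21 lower in each allele by itself. Independent lists of these sizes would share 1.12 and 0.618. In 20 simulations of unchanged groups with simulated, shared yw arrays the mean was 0 and 0.050, where few calls are left to share. The covariance of the alleles' log2 differences was 0.162, against 0.122 simulated. Their correlation was 0.453, below the simulated 0.503. The 2 yw arrays were not split between the alleles at this stage, so part of the overlap may come from the shared controls. For EY03052 the median over all probe sets was 0.059, and -0.12 with each array centred on its median. The f01000 count was 315 without yw stage 14 replicate 1 and 286 without yw stage 14 replicate 2. It was 293 without f01000 stage 14 replicate 1. The EY03052 count was 53 without yw stage 14 replicate 1 and 41 without EY03052 stage 14 replicate 1. It was 43 without EY03052 stage 14 replicate 2. The count between alleles was 175 without f01000 stage 14 replicate 2 and 108 without EY03052 stage 14 replicate 1. It was 139 without EY03052 stage 14 replicate 2.

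Whether the mutant difference itself changed between stages was tested directly. Muc4B passed between stages 12 and 10B: both alleles together were higher by 4.21 at stage 10B and differed by 0.029 (adjusted p = 0.99) at stage 12, an interaction of -4.18 (adjusted p = 0.016). Muc4B was the 1 probe set that passed in limma between these stages, where 409 had an unadjusted p under 0.05. Between stages 14 and 12 limma called 0, and 509 had an unadjusted p under 0.05. Both 409 and 509 are below the share of 0.05 of the 13223 tested probe sets that chance alone would give. The count between stages 12 and 10B was 0 without yw stage 10B replicate 1 and 4 without yw stage 10B replicate 4. It was 0 without yw stage 12 replicate 1 and 0 without yw stage 12 replicate 2. It was 0 without f01000 stage 10B replicate 1 and 55 without f01000 stage 12 replicate 1. It was 0 without EY03052 stage 10B replicate 1 and 0 without EY03052 stage 12 replicate 1. It was 0 without EY03052 stage 12 replicate 2. That between stages 14 and 12 was 1 without yw stage 14 replicate 1 and 36 without f01000 stage 12 replicate 1. It was 1 without f01000 stage 14 replicate 1.

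Genes of the yw course were followed as lists in the mutants, with lists drawn from stages whose arrays did not enter the mutant comparison. The 557 probe sets that rose by at least 2-fold from stage 9/10A to 12 in yw had a median log2 difference of 0.10 (adjusted p = 5.6e-04, and adjusted p = 0.34 with an estimated correlation) in both alleles at stage 10B; 59 of them were higher and 10 lower. The medians were -0.00027 (adjusted p = 0.045, and adjusted p = 0.52 with an estimated correlation) in f01000, where the test pointed up and the median lay just below 0, and 0.21 (adjusted p = 2.5e-04, and adjusted p = 0.34 with an estimated correlation) in EY03052. Over the arrays, the mean list score was higher by 0.29 in the 4 mutant than in the 4 yw arrays (p = 0.057, exact two-sided permutation test, smallest possible p = 0.029). This test exchanged arrays across signal ranges. In the lower range the scores were 7.16 and 7.31 in f01000 and 6.80 and 6.91 in yw. In the wider range they were 7.25 and 7.38 in EY03052 and 7.08 and 7.16 in yw. Within 1 signal range, the medians were 0.11 for f01000 and 0.13 for EY03052. With the range as a block the list, then of 610 probe sets, had a median of 0.11 (adjusted p = 0.0015, and adjusted p = 0.40 with an estimated correlation). The 377 probe sets that fell in yw over the same stages had a median of 0.061 (adjusted p = 0.013, and adjusted p = 0.34 with an estimated correlation), and their score differed by 0.15 (p = 0.34, exact permutation test). By allele the medians were 0.33 (adjusted p = 5.8e-10, and adjusted p = 0.082 with an estimated correlation) in f01000 and -0.10 (adjusted p = 2.5e-04, and adjusted p = 0.32 with an estimated correlation) in EY03052. With the range as a block they were 0.19 (adjusted p = 4.1e-04, and adjusted p = 0.26 with an estimated correlation) and -0.0080 (adjusted p = 0.95, and adjusted p = 0.97 with an estimated correlation): by the preset correlation f01000 passed with and without the block, EY03052 only without it. The fell list had a median of 0.081 (adjusted p = 0.20) without yw stage 10B replicate 3, 0.011 (adjusted p = 0.36) without yw stage 10B replicate 4 and 0.033 (adjusted p = 0.062) without f01000 stage 10B replicate 2.

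At stage 12, the 208 probe sets that rose from stage 10B to 14 in yw had a median of 0.38 (adjusted p = 1.3e-07, and adjusted p = 0.14 with an estimated correlation) in both alleles, 0.63 (adjusted p = 6.6e-11, and adjusted p = 0.13 with an estimated correlation) in f01000 and 0.083 (adjusted p = 0.29, and adjusted p = 0.73 with an estimated correlation) in EY03052. In both alleles together 5 were higher and 1 lower. With the signal range as a block, the list then of 116 probe sets, the medians were 0.41 (adjusted p = 6.4e-10, and adjusted p = 0.055 with an estimated correlation) in both alleles and 0.74 (adjusted p = 2.8e-14, and adjusted p = 0.035 with an estimated correlation) in f01000. The 317 that fell over those stages had a median of 0.21 (adjusted p = 3.8e-05, and adjusted p = 0.14 with an estimated correlation), so lists of both directions pointed up. At stage 14, the lists of 156 and 142 probe sets that rose and fell from stage 10B to 12 had medians of -0.063 (adjusted p = 0.13, and adjusted p = 0.74 with an estimated correlation) and 0.17 (adjusted p = 0.053, and adjusted p = 0.74 with an estimated correlation). In f01000 at stage 14 the fell list had a median of 0.37 (adjusted p = 2.8e-05, and adjusted p = 0.51 with an estimated correlation). Without f01000 stage 14 replicate 2 the stage 14 rose list turned up, to 0.11 (adjusted p = 0.84), and without yw stage 14 replicate 1 it was -0.0076 (adjusted p = 0.57). It came to -0.077 (adjusted p = 0.013) without yw stage 14 replicate 2, -0.26 (adjusted p = 7.2e-05) without f01000 stage 14 replicate 1 and -0.14 (adjusted p = 0.020) without EY03052 stage 14 replicate 2, and the fell list to 0.25 (adjusted p = 3.7e-04) without yw stage 14 replicate 1, 0.12 (adjusted p = 0.029) without f01000 stage 14 replicate 1 and 0.21 (adjusted p = 0.014) without EY03052 stage 14 replicate 1.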

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

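The tests of mixed stages and of RNA quality, and the comparison of the list with all probe sets within a signal range, were chosen after the results were seen; those of other splits, of the signal range itself and of linkage were not. Gaps between arrays are given below as parts of the range of the log2 values, while the signals beside them are on the linear scale. In yw stage 10B, the 1 group of 4 arrays, Yp2 was 10370.1 in yw stage 10B replicate 3 and 5409 to 5749 in the other 3, a gap of 0.906 of the range. sad was 7.81 in yw stage 10B replicate 3 and 1.02 to 1.46 in the other 3, a gap of 0.906 of the range. fng was 2.97 in yw stage 10B replicate 4 and 26.0 to 32.8 in the other 3, a gap of 0.873 of the range. CG42857 was 3.97 in yw stage 10B replicate 1 and 1.11 to 1.32 in the other 3, a gap of 0.912 of the range. These 4 of 177 named genes had such a gap, of a size that chance alone gives in about 1 in 20 groups. That is no more than this rate gives, so outlying arrays are not shown by these genes. The rate takes the 4 arrays as alike, while they came in 2 pairs of unlike signal range. The test therefore cannot show that outlying arrays are absent.

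Muc4B was the 1 probe set whose mutant difference changed between stages 10B and 12, by -4.18. The alleles differed from each other in 1418 probe sets at stage 10B, 578 at stage 12 and 408 at stage 14, and in 95 at stage 10B with the signal range as a block. Control probe sets outside the comparisons had an Act5C 3' over 5' ratio of 24.1 in f01000 stage 12 replicate 2, an eIF-4a ratio of 7.89 against 2.00 to 3.67 elsewhere, and a GAPDH ratio of 5.32 against 2.69 to 4.20.

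The count for both alleles at stage 10B was set against other splits of the 8 arrays into 4 and 4, with 1 mean per side. The real split gave 263 probe sets, and 2 of the 35 splits, the real one included, gave as many, so chance was not excluded by this share. The highest other split gave 2343 and is the one that follows the signal range, several times the real count, which points to that structure of the arrays; the next gave 4. With the range as a block the real split gave 492 and the highest other of 18 splits 4, and 18 splits are too few for a share under 0.05.

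The first pattern weighed is that genes rising by stage 12 in yw had higher values in the mutants at stage 10B, a shift that the estimated correlation and the permutation test left short of the threshold. Each side of this comparison holds 2 arrays of each signal range, so a range effect alike in all genotypes cancels, and within 1 range the list's median was 0.113 for f01000 and 0.125 for EY03052, against 0.0678 and 0.0841 between the 2 yw arrays of that range. This argues against the signal range as the whole cause, though with the shift of all probe sets taken off, a step added after the values were seen, f01000 kept 0.0689, barely over its bound, and EY03052 0.110, the lowest single pairs of arrays gave 0.0486 and 0.0402, and the list that fell in yw was at 0.186 in f01000, so that its shift was not particular to rising genes. Stage 12 follicles among those of stage 10B may account for each allele's shift of the rising genes within its range. Over 117 genes the implied share of stage 12 RNA had a median of 22.8% in f01000 and 5.22% in EY03052. A part of 0.265 and 0.154 of the genes (31 and 18) lay over 2 SE from it. No chance level was computed for this scatter, and only most of the genes was to count as excluding 1 share. It therefore neither excludes nor shows 1 share. In f01000, 0 of the genes stayed over 2 SE below the level from the lowest share taken, 4.76%. That share was a median over the list, unlike the share set by Cp15, Cp16 and Cp18 in the second pattern. Stage 12 follicles would also lower the genes that fall by stage 12 in yw. Within its range that list was at 0.186 in f01000, against 0.0024 between the 2 yw arrays. This argues against such follicles as the only cause in f01000, though with the block and an estimated correlation that rise did not pass (adjusted p = 0.26). In EY03052 the list was at -0.0146, against 0.0892 between its yw arrays, which decides nothing. An earlier start of the stage 12 genes in pxt mutants stays open and untested.

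The second pattern is the high late chorion genes in f01000 at stage 12. Stage 14 follicles like those on the arrays would bring their other transcripts too. Cp15, Cp16 and Cp18 allow no share under 26.9% of yw stage 14 RNA, or under 72.0% of f01000 stage 14 RNA. Of 63 genes that rise from stage 12 to 14 in yw, 11 stayed over 2 SE below the level from either source. Chance gives 1.43. Ilp8 was at 8.14 where 178 was needed and Tg at 1.35 where 29.5 was, which argues against such follicles as the whole cause, though the median implied share was 29.5%, 0.541 of that of Cp15. Without f01000 stage 12 replicate 2 the log2 differences of Cp15 and Cp18 were 5.51 and 3.55 (adjusted p = 0.0023 and 0.031), which argues against lower RNA quality of that array as their cause; that of Cp16 went from 2.45 ± 0.60 to 2.55 ± 0.74 (adjusted p = 0.059), where the call ended because the SE grew with 1 array less, so for Cp16 alone nothing was decided. Follicles of a stage between 12 and 14, of which this series holds no arrays, and a stage 12 that runs late in f01000 stay open and untested.

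The third pattern is the genes that differ from yw in both alleles at every stage. If the mutants shared a chromosome segment around Pxt, its neighbours would be among them, but 0 of the 100 nearest measured genes were, against 29 of 9243 elsewhere (Fisher's exact one-sided p = 1). With 100 neighbours that test has little power, yet 24 of the 29 genes lie on other chromosome arms than Pxt, which argues against linkage as the whole cause. Unlinked differences in genetic background between yw and the mutant stocks, and an effect of pxt, stay open, and neither was tested.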

How the results depend on the processing

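The signal range block, the wider range alone and the 3' to 5' covariate were chosen after seeing the data; the other alternatives were planned. Counts of changed probe sets not listed here stayed within 1.5 times, and lists of the yw course in both alleles together not listed here kept their direction and side of the threshold; single genes and gene lists that lost calls are counted at the end. Where no reason stands beside a value, the cause was not tested.

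With median centring the counts that moved by over 1.5 times were 1160 (yw 10B against 9/10A), 322 (both alleles 10B), 115 (both alleles 12), 107 (both alleles 14), 704 (f01000 10B), 535 (f01000 12), 224 (f01000 14), 106 (EY03052 10B), 52 (EY03052 14), 509 (f01000 against EY03052 10B), 225 (f01000 against EY03052 12) and 171 (f01000 against EY03052 14), and the stage lists that changed had a median of 0.0271 (fell list, both alleles 14, adjusted p = 0.038). With a pseudocount of 1 the stage lists that changed had a median of 0.208 (fell list, both alleles 14, adjusted p = 0.026). Without a filter the stage lists that changed had a median of 0.178 (fell list, both alleles 14, adjusted p = 0.032). With the stricter filter the stage lists that changed had a median of 0.158 (fell list, both alleles 14, adjusted p = 0.017). Without the intensity trend the counts that moved by over 1.5 times were 177 (both alleles 12), 358 (f01000 14), 53 (EY03052 14), 342 (f01000 against EY03052 12), 209 (f01000 against EY03052 14) and 0 (the change between 10B and 12). With the replicate number as a block, which leaves the yw stage 10B mean to its 2 arrays of the lower signal range, the counts that moved by over 1.5 times were 1356 (yw 12 against 10B), 780 (f01000 10B), 952 (EY03052 10B) and 9 (the change between 10B and 12), and the stage lists that changed had a median of 0.0129 (fell list, both alleles 10B, adjusted p = 0.16, direction turned) and a median of 0.128 (fell list, both alleles 14, adjusted p = 0.011). With the compared groups alone, so fewer arrays behind the spread, the counts that moved by over 1.5 times were 119 (both alleles 12), 102 (both alleles 14), 64 (f01000 12), 245 (f01000 14), 101 (EY03052 10B), 289 (EY03052 12), 53 (EY03052 14), 2681 (f01000 against EY03052 10B), 34 (f01000 against EY03052 12), 218 (f01000 against EY03052 14) and 5 (the change between 10B and 12). At a fold of at least 2 the counts that moved by over 1.5 times were 657 (yw 10B against 9/10A), 298 (yw 12 against 10B), 201 (both alleles 10B), 128 (both alleles 12), 113 (both alleles 14), 466 (f01000 10B), 488 (f01000 12), 291 (f01000 14), 97 (EY03052 10B), 586 (f01000 against EY03052 10B), 257 (f01000 against EY03052 12) and 201 (f01000 against EY03052 14). With the estimated correlation the lists below lost their calls with unchanged medians: a median of 0.102 (rose list, both alleles 10B, adjusted p = 0.34), a median of 0.0614 (fell list, both alleles 10B, adjusted p = 0.34), a median of 0.378 (rose list, both alleles 12, adjusted p = 0.14) and a median of 0.215 (fell list, both alleles 12, adjusted p = 0.14). With the signal range as a block the counts that moved by over 1.5 times were 248 (yw 12 against 10B), 849 (f01000 10B), 74 (EY03052 10B) and 95 (f01000 against EY03052 10B). With the 3' to 5' ratio as a covariate the counts that moved by over 1.5 times were 555 (f01000 12) and 262 (f01000 against EY03052 12). With the wider range alone, so fewer arrays, the counts that moved by over 1.5 times were 176 (yw 12 against 10B) and 53 (EY03052 10B).

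Leaving out 1 array at a time, where a group of 2 then keeps 1 array assumed to vary like the others, gave counts of 656 to 2201 (yw 10B against 9/10A), 191 to 653 (yw 12 against 10B), 312 to 493 (both alleles 10B), 466 to 1257 (f01000 10B), 68 to 255 (EY03052 10B), 0 to 55 (the change between 10B and 12), 123 to 206 (yw 14 against 12), 70 to 845 (both alleles 12), 339 to 1786 (f01000 12), 33 to 44 (EY03052 12), 0 to 36 (the change between 12 and 14), 98 to 281 (both alleles 14), 286 to 427 (f01000 14), 41 to 67 (EY03052 14), 305 to 646 (f01000 against EY03052 10B), 128 to 1353 (f01000 against EY03052 12) and 108 to 317 (f01000 against EY03052 14). The medians of the stage lists were 0.0599 to 0.144 (rose list, both alleles 10B), 0.0108 to 0.106 (fell list, both alleles 10B), 0.270 to 0.377 (rose list, both alleles 12), 0.142 to 0.279 (fell list, both alleles 12), -0.260 to 0.107 (rose list, both alleles 14) and 0.0842 to 0.25 (fell list, both alleles 14).

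The replicate numbers do not pair the arrays: over 45 pairs of groups the deviations of same-numbered arrays correlated at -0.270 to 0.166, 2 above 0.1, so the block removes no known pairing. Replicates 3 and 4 exist in yw stage 10B alone, where the block takes up their values. The yw stage 10B mean then rests on replicates 1 and 2, both of the lower signal range. Comparisons with yw stage 10B under this block are therefore comparisons with that range. Among named genes that passed, 2387 values kept their call under the other settings and 280 lost it; with 1 array left out 1252 kept it and 294 lost it. For the gene lists the same numbers were 293 and 46, and 134 and 22. me31B turned direction, from -0.73 for yw 10B against 9/10A to 0.0792 with quantile normalization; the cause was not tested. Without detection calls, signals near background cannot be told from absence, which limits what low levels such as that of fng at stage 10B can show.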

Other observations

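In yw, Cyp18a1, which encodes an ecdysone-inactivating enzyme, rose from stage 9/10A to 10B by 1.49 ± 0.26 on the log2 scale, and at stage 10B the mean of both alleles was lower than yw, at -1.10 ± 0.21 (adjusted p = 0.0027); its second probe set gave -2.07. By allele Cyp18a1 was at -1.02 (adjusted p = 0.012) in f01000 and -1.17 (adjusted p = 0.020) in EY03052, and with the signal range as a block neither passed (adjusted p = 0.068 and 0.063). The BMP receptor gene tkv was higher at stages 10B (0.71) and 12 (0.82). Its adjusted p was past 0.05 at both with median centring, and its second probe set did not pass (0.17 and 0.37). Of 15 egg activation and meiosis genes, 5 rose and 2 fell (7 and 3 adjusted over the list alone) from stage 9/10A to 10B in yw (set test adjusted p = 0.095, adjusted p = 0.32 with an estimated correlation), with fzy at 1.38, bora at 1.38 and twe at 1.09; the other probe sets of fzy did not pass, at -0.12 to 0.19. The maternal genes krimp (1.28) and osk (-0.72) moved in opposite directions in that step. By adjusted p, bora and osk had 0.082 to 0.14 without yw stage 9/10A replicate 1, and tkv had 0.40 without yw stage 12 replicate 1 at stage 12.

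Among markers of other cell types, the muscle gene Prm went up and down through the yw course, by 2.11 from stage 9/10A to 10B, -3.45 to stage 12 and 2.12 to stage 14. Its second probe set, at 1.32, -2.11 and 1.64, passed only in the fall. The muscle list passed in none of these steps (set test adjusted p = 0.58, 0.50 and 0.27). The fat body list gene Npc2e differed by -1.57 in the first step (adjusted p = 0.035, and adjusted p = 0.23 with the signal range as a block). By adjusted p, Npc2e had 0.057 to 0.22 without yw stage 9/10A replicate 1 or 2 or yw stage 10B replicate 1, 2 or 4; for the last step, Prm had 0.077 without yw stage 14 replicate 2.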
